A study of Mus musculus with 17 samples.

How the data were processed

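The series followed gene expression in the dorsal and lateral lineages of the postnatal neurogenic system that runs from the subventricular zone (SVZ) along the rostral migratory stream to the olfactory bulb. Per the labels, progenitors of the dorsal or the lateral SVZ wall of CD1 mice were electroporated in vivo at postnatal day 1, and GFP-positive cells were isolated by fluorescence-activated cell sorting at 8 hours or 1, 2, 4, 7 or 14 days. The series held 17 Agilent arrays of 2 colours, with 2, 3, 2, 3, 3 and 4 arrays at the 6 time points in that order. On every array the dorsal sample carried Cy3 and the lateral sample of the same time point carried Cy5, and the dyes were never swapped. A constant dye effect of a probe therefore adds to each dorsal-lateral difference, whereas it cancels in changes of that difference with time and in comparisons of time points within a dye. Per the labels' protocols, mRNA was isolated with magnetic beads and its cDNA was amplified by a commercial global PCR service (SuperAmp) whose protocol was not disclosed, and 200 ng of each amplified cDNA was labelled. The labels name the RNA of channel 1 polyA RNA and that of channel 2 total RNA. They call the arrays of a time point biological replicates, and the p-values measure the spread between these replicates.

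Spot values were fluorescence intensity on a linear scale, and per the file headers the authors extracted them with Agilent Feature Extraction 10.5.1.1 or 10.7.3.1. The mean signal and the median local background of each channel were used. The scanner software's processed signals, deposited in the same files as intensity after background subtraction and dye normalization, served as an alternative, and its log10 ratio of red over green, per the file headers, served only to find the scale of the deposited value table. That table, deposited for the series, was found to hold log2 values of Cy3 over Cy5: its columns correlated with the scanner's red over green ratio at r of -0.90 to -0.97 across 41267 matched probes (genes within 1 array, not independent replicates). On probes well above background and over 1000 in both channels its slope on that log10 ratio was -3.25 to -3.53, where log2 values give -3.32 and natural logs -2.30, and on all matched probes it was -2.63 to -3.27. Its medians were -0.0095 and -0.0094 at 8 hours, -0.0222, -0.0712 and -0.0564 at 1 day, -0.0271 and -0.0326 at 2 days, -0.0052, 0.0459 and -0.0211 at 4 days, -0.0135, -0.0340 and -0.0134 at 7 days, and -0.0920, -0.164, 0.0028 and 0.0015 at 14 days. Scale and direction were thus settled, the columns were centred near 0, and the normalization that gave them is not given in the sources used here. The table was used only as an alternative for the wall differences.

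Each array held 43379 spots that were not controls, for 41174 probes, besides 1639 control spots. A total of 26876 probes were named through a RefSeq accession and 3241 through a symbol or synonym in a table of the GRCm38.p6 assembly, used for names only, and 11057 kept the name in the files. Background was corrected with normexp (offset 50) on all spots. Log ratios were normalized by loess within arrays with control spots at weight 0, and the mean log2 intensities by quantiles between arrays (Aquantile). Spots with an outlier flag were set to missing, which were 0.32 to 2.61% of spots per array, and no spot was saturated. Spots of a probe were averaged, and the probe with the highest mean signal represented a gene. Probes well above background in either channel on at least 2 arrays were kept (36785 probes), giving 26458 genes for testing and 26414 in comparisons that involve 14 days, where the others had no measurement. Other probes of a gene entered through an alternative that averaged them.

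Wall differences were tested on the within-array log2 ratio, dorsal minus lateral, as the equal-weight mean of the 6 time points, at each time point, and as an F test for a change with time. Time was tested as 14 days against 8 hours in each wall, and on the mean of both walls as an F test over the 6 time points and as each of the 5 steps between neighbouring times. All 17 arrays entered 1 fit with a mean per time point in limma 3.58.1 (lmFit and eBayes) under R 4.3.3 with data.table (1.17.8). P-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes of a comparison, with a threshold of 0.05. All adjusted p-values of genes are from limma. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

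Where a gene was well above background on no array of a group, only a bound was given, as "at least": the mean of the brighter group against the mean, per array, of the higher of the lowest signal among probes well above background and the probe's own signal. Such bounds are open to dye bias. The pooled spread is an average over time points, and the log ratios of 1 day and 14 days had variances of 2.60 and 2.25, against 0.912 at 8 hours and 1.15 to 1.22 at 2, 4 and 7 days.

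A total of 24 gene lists were fixed before the data were examined: pallial, subpallial, and Zic and septal transcription factors; dopaminergic periglomerular, GABAergic and olfactory interneuron, glutamatergic neuron, radial glia and stem cell, astrocyte, proliferation, transit amplifying progenitor, neuroblast, mature neuron and synapse, oligodendrocyte lineage, ependymal, microglia, endothelial and mural, choroid plexus, erythroid, immediate early and stress, Wnt, Shh and Notch pathway, sex-linked, and reference genes. Lists share some members. Each was tested against all other genes with camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation, p-values adjusted over the 24 lists of a comparison. Missing values were filled from the fit for this test alone. Of 336 pairs of list and comparison, 131 were called with the preset correlation and 36 with the estimated one, and the text leads with the latter. Counts of called members "adjusted over the list alone" use the Benjamini-Hochberg method within a list.

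Genes were named by a rule fixed before the data were examined, leaving out clone and predicted names: for the mean wall difference the 10 largest in each direction with the same sign at all 6 time points, at each time point and step the 3 largest in each direction, for changes of the wall difference with time the 10 smallest p-values, for 14 days against 8 hours the 10 largest in each direction called in both walls and ranked by the smaller size, and up to 4 members of each list with the smallest p-values. All members of the pallial, subpallial, Zic and dopaminergic lists could be named. Some genes the rule names are not reported here. Genes outside the rule are said to have been chosen after their values were seen.

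Alternatives were the scanner's processed signals, no background correction, the value table, median centring in place of loess, quantile normalization of all 34 channels, no filter and a stricter filter (well above background in both channels on at least 9 arrays), the mean over probes, trend and robust eBayes, array weights, the replicate number or letter as a block, the slide as a block, only the arrays of the contrast, and leaving out each array. Leaving out 2 arrays that stand apart was added after the data had been seen. The arrays lay on 5 slides. Slides 2 and 3 each held 1 array of 2, 4 and 7 days, and slide 5 held both 8-hour arrays and 1 array each of 4 and 7 days. The 1-day arrays filled slide 1 and the 14-day arrays slide 4, so these time points and their slides cannot be told apart. The slide was a fixed block for the steps from 2 to 4 and from 4 to 7 days, and a random block otherwise.

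Fits were tested on data simulated from each gene's residual spread with known changes added. For the mean wall difference, 44.8, 88.1 and 100% of changes of 1, 2 and 4 log2 units were found. At 8 hours these were 5.97, 29.9 and 57.6%, at 1 day 16.4, 29.9 and 72.7%, at 2 days 8.96, 31.3 and 51.5%, at 4 days 10.4, 32.8 and 68.2%, at 7 days 14.9, 28.4 and 62.1%, and at 14 days 13.4, 38.8 and 77.3%. The few arrays limit precision, and the pooled spread may overstate recovery at 1 and 14 days.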

Results

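Expression was compared between cells derived from the dorsal and the lateral wall of the postnatal subventricular zone, a region whose progenitors make neurons and glia for the olfactory bulb and forebrain. Each of the 17 arrays held 1 dorsal and 1 lateral sample of GFP-positive sorted cells from the same time after electroporation, with 2 arrays at 8 hours, 3 at 1 day, 2 at 2 days, 3 at 4 days, 3 at 7 days and 4 at 14 days. Between 41.5 and 77.0% of probes were well above background in the dorsal samples and between 56.8 and 79.7% in the lateral ones. The median signal ran from 30.3 to 310 in the dorsal channel and from 122 to 601 in the lateral channel. The arrays of 1 day replicate 1 and 14 days replicate 2 stood apart, with median correlations of 0.69 and 0.77 to the other arrays (across genes, which are not independent replicates). Replicates of a time point correlated across genes at a mean r of 0.98, 0.82, 0.97, 0.95, 0.95 and 0.82 from 8 hours to 14 days in the mean of both walls. Their dorsal-lateral log ratios correlated at 0.40 at 8 hours and 0.38 at 2 days, but at 0.08, 0.05, 0.09 and 0.03 at 1, 4, 7 and 14 days, against 0.05 between arrays of different times. Differences below are log2 values ± SE, and a positive wall difference means a higher level in the dorsal sample. Genes are given by the array's symbols, updated by accession.

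The first comparison asked which genes separated the walls as a mean over the 6 time points (n = 17 arrays). Transcription factors of the pallium, the territory of the cortex, were higher in the dorsal lineage. Of 15 measured factors 7 were called higher and 0 lower (14 higher adjusted over the list alone), with a list median of 1.31 (camera adjusted p = 0.0027 with an estimated correlation). Tfap2c, an AP-2 factor of cortical progenitors, was 3.22 ± 0.48 higher (9.35-fold, adjusted p = 0.0059, 14 of 17 arrays). Tbr1, a factor of glutamatergic cortical neurons, was 3.12 ± 0.49 (adjusted p = 0.0080, 11 of 17) and Dmrta2, a factor of cortical patterning, 2.34 ± 0.22 (adjusted p = 0.0013, 14 of 17). Subpallial factors were lower. Of 17 measured factors 4 were called lower and 0 higher (5 lower adjusted over the list alone), with a median of -0.54 (adjusted p = 0.0027 with an estimated correlation). Among these homeobox factors of ventral forebrain progenitors, Dlx2 differed by -1.98 ± 0.12 (3.95-fold, adjusted p = 1.13e-05, 15 of 17 arrays). Dlx1 differed by -1.90 ± 0.28, Vax1 by -1.81 ± 0.35 and Gsx2 by -0.70 ± 0.10. Of 7 Zic and septal factors, 2 were called higher (3 adjusted over the list alone; median 0.44, adjusted p = 0.0183 with an estimated correlation). Zic2 was 3.11 ± 0.44 and Zic1 2.25 ± 0.34 higher, both on 16 of 17 arrays.

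Radial glia, astrocyte and proliferation genes also differed between the walls. Radial glia and stem cell genes were higher in the dorsal samples (3 of 17 called, 8 adjusted over the list alone, median 0.63, adjusted p = 0.0122 with an estimated correlation). Among them were the matrix glycoprotein Tnc (2.50 ± 0.41) and the fatty acid binding protein Fabp7 (1.63 ± 0.25). So were astrocyte genes (4 of 12 called, 9 adjusted over the list alone, median 1.15, adjusted p = 0.0123 with an estimated correlation), with Mlc1 at 1.49 ± 0.15 and the glycolytic enzyme Aldoc at 1.66 ± 0.27. Proliferation genes were lower in the dorsal samples (2 of 16 called, 11 adjusted over the list alone, median -0.85, adjusted p = 0.0188 with an estimated correlation), such as the mitotic kinase Aurkb at -0.99 ± 0.15. Erythroid genes moved with these groups and were higher in the dorsal samples (1 of 6 called, 3 adjusted over the list alone, median 1.56, adjusted p = 0.0283 with an estimated correlation). The globin Hbb-bt differed by 3.70 ± 0.51, on 10 of 14 arrays. For the erythroid list the adjusted p with an estimated correlation was 0.121 without 14 days replicate 2 (median 0.89), 0.053 without 14 days replicate 4 and 0.163 without both arrays that stand apart (median 0.95). It was 0.0515 with no filter (median 0.97), and 0.0552 to 0.113 with array weights, the mean over probes and the value table. With median centring in place of loess no list was called with an estimated correlation. Its median and adjusted p were 0.89 and 0.0651 for pallial, -0.75 and 0.152 for subpallial and 0.52 and 0.152 for Zic factors. They were -0.08 and 0.930 for radial glia, 0.40 and 0.328 for astrocyte, -1.52 and 0.170 for proliferation and 1.35 and 0.152 for erythroid genes. The fits lost a few of these calls when 1 array was left out. These were Aldoc (adjusted p = 0.0521) and Fabp7 (0.0507) without 2 days replicate 1, and Vax1 without 8 hours replicate 1, 8 hours replicate 2 or 2 days replicate 1 (0.0552, 0.0663 and 0.0741).

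Other lists were not called in the mean wall difference with an estimated correlation. Glutamatergic neuron genes had 3 of 10 members called higher (5 adjusted over the list alone; median 0.71, adjusted p = 0.106 with an estimated correlation), including Slc17a6, a vesicular glutamate transporter, at 3.08 ± 0.51. Ependymal genes had 8 of 11 members higher adjusted over the list alone (median 1.32, adjusted p = 0.0881 with an estimated correlation), and transit amplifying genes 5 of 12 lower (median -0.71, adjusted p = 0.065). The GABAergic and olfactory interneuron list was split, with 3 of 11 members higher and 5 lower adjusted over the list alone (median -0.49, adjusted p = 0.313). Medians and adjusted p with an estimated correlation were -0.20 and 0.438 for neuroblast, 0.20 and 0.473 for mature neuron, 0.63 and 0.371 for oligodendrocyte, 0.43 and 0.371 for Notch and 0.25 and 0.118 for Shh genes, and 0.24 and 0.602 for immediate early genes. They were 0.07 and 1.00 for microglia, 0.10 and 0.856 for endothelial, 0.33 and 0.841 for choroid plexus, -0.17 and 0.653 for sex-linked and -0.19 and 0.150 for reference genes. For dopaminergic genes (median -0.01, mean 0.08, adjusted p = 0.908) and Wnt pathway genes (median 0.00, mean 0.11, adjusted p = 0.804) the median and mean differed in sign.

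Across all genes 629 were called in the mean wall difference, 341 higher and 288 lower. The largest other genes with the same sign at all 6 time points were Fezf2, a zinc-finger factor of forebrain patterning, at 3.05 ± 0.39 (8.27-fold, adjusted p = 0.0032), and Cyp1b1, a cytochrome P450, at 2.91 ± 0.53. Cntnap2, a neurexin-family protein, lay at 2.68 ± 0.45, the protease Adamts9 at 2.38 ± 0.48 and the protocadherin Pcdh8 at 2.36 ± 0.29 (adjusted p = 0.0031). On the lateral side were Bcl11b, a zinc-finger factor, at -2.22 ± 0.44, Arhgef39 at -2.22 ± 0.41, and Uhrf1, a cofactor of maintenance DNA methylation, at -1.76 ± 0.36. Further ones were Runx1t1 at -1.74 ± 0.24, Dcbld1 at -1.64 ± 0.30, Abracl at -1.55 ± 0.22 and the ribosomal Rpl32 at -1.55 ± 0.27. Calml4 (2.41 ± 0.54) was called in 5 of the 17 fits that left out 1 array, Uhrf1 in 11, Bcl11b in 12, Adamts9 in 13, Cyp1b1, Arhgef39 and Dcbld1 in 15 and Rpl32 in 13 of 16. Without 8 hours replicate 1 the adjusted p was 0.0535 for Cyp1b1, 0.0617 for Arhgef39, 0.0704 for Rpl32 and 0.0917 for Adamts9. Without 2 days replicate 1 it was 0.0547, 0.0538, 0.0693 and 0.0817, and 0.0521 for Dcbld1. The count was 230 and 346 without 8 hours replicate 1 and 2, and 213 without 2 days replicate 1. It was 396 and 403 without 4 days replicate 1 and 3, 389, 357 and 356 without 7 days replicate 1, 2 and 3, and 1152 without 1 day replicate 1. Median centring called 1712 higher and 4434 lower genes, 468 of them shared with the 629. The slide as a random block called 3293 at a consensus correlation of -0.17.

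**Figure D1:**
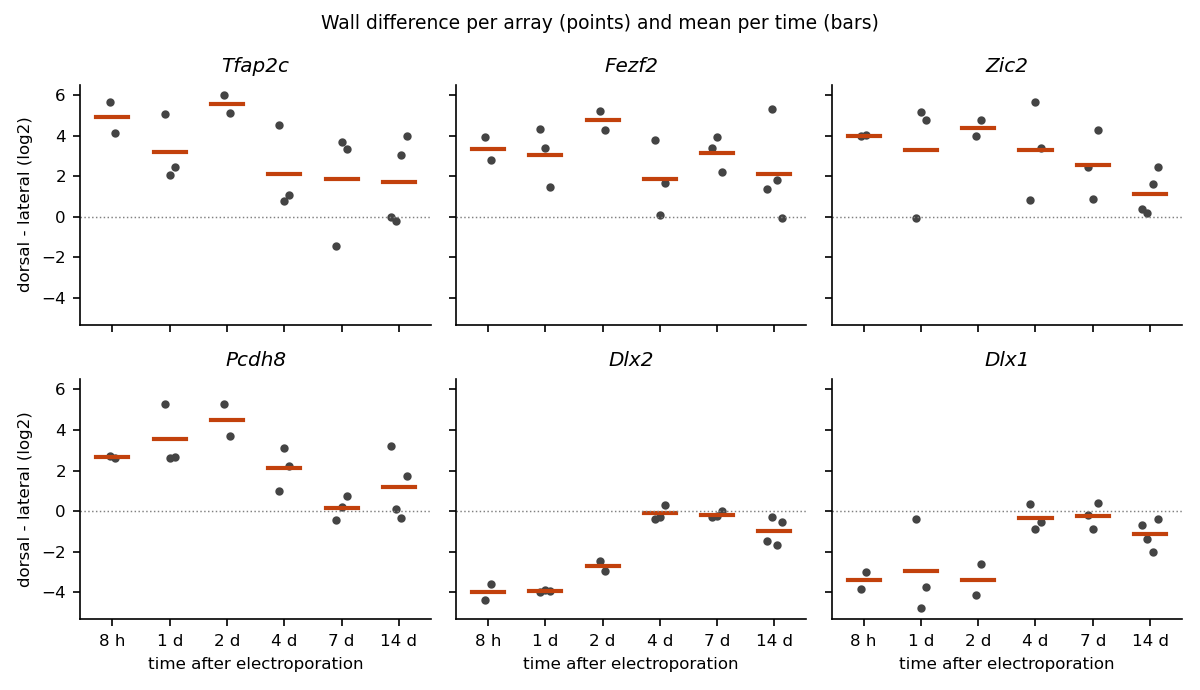
Wall difference (log2, dorsal minus lateral) of Tfap2c, Fezf2, Zic2, Pcdh8, Dlx2 and Dlx1 on each array by time after electroporation; points are arrays and bars the mean of a time point. Dlx2 lay at a mean of -3.99 at 8 hours, -3.94 at 1 day and -2.71 at 2 days, and at -0.10 at 4 days.

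At 8 hours (n = 2 arrays) 100 genes were called, 74 higher in the dorsal and 26 higher in the lateral samples. Dct, an enzyme of melanin synthesis, was 5.08 ± 0.75 higher in the dorsal samples (33.8-fold, adjusted p = 0.0092). The membrane repair protein Dysf was 4.65 ± 0.62 higher, Dmrta2 4.30 ± 0.64, and the laminin Lama1 at least 16.8-fold, as it was not well above background in the lateral samples. Dlx2 (-3.99 ± 0.33, 15.9-fold, adjusted p = 0.00034) and the adhesion receptor Adgrf5 (-3.25 ± 0.38) were higher in the lateral samples. The chemokine Ccl11 was at least 8.40-fold higher there, where the dorsal samples were not well above background. Pallial factors (median 1.12), radial glia genes (1.31) and erythroid genes (4.96, 5 of 6 members adjusted over the list alone) were higher and subpallial factors (-0.47) lower in the dorsal samples, each with adjusted p = 0.0193 with an estimated correlation. Of other cell types, endothelial genes had a median of -1.13 with 3 of 15 lower adjusted over the list alone (adjusted p = 0.175 with an estimated correlation), and microglia genes one of -1.47 (adjusted p = 0.259). Choroid plexus genes had a median of -0.46 and a mean of 0.13, and mature neuron genes -0.25 and 0.19. Without 8 hours replicate 2 the adjusted p with an estimated correlation was 0.164 for pallial, 0.0771 for subpallial, 0.0777 for radial glia and 0.0777 for erythroid genes. The count was 190 without replicate 2 and 63 without replicate 1. Dysf (0.0879) and Ccl11 (0.0745) lost the call without 8 hours replicate 1. Dct (0.114 and 0.0983) and Dmrta2 (0.170 and 0.0602) lost it without either replicate, and Lama1 was called in 4 of the 17 fits. Median centring called 54 higher and 70 lower genes and none of the 4 lists (adjusted p of 0.170 to 0.929, with a radial glia median of 0.12). With the value table the calls were 3 and 3, and erythroid genes had an adjusted p of 0.107.

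At 1 day (n = 3) 292 genes were called, 183 higher and 109 lower in the dorsal samples. Lgi2, a secreted leucine-rich protein, was 5.40 ± 1.03 higher (42.1-fold, adjusted p = 0.0286). Dct was 4.66 ± 0.62 higher, the homeobox factor Prrx2 4.65 ± 0.47 and Pcp4, a calmodulin-binding protein, 4.26 ± 0.59. The centromere protein Cenpb (-4.80 ± 0.93), Uhrf1 (-4.19 ± 0.84), Dlx2 (-3.94 ± 0.27, adjusted p = 6.9e-05), Aurkb (-3.05 ± 0.34) and Gsx2 (-1.40 ± 0.23) were lower. Pallial factors had a median of 1.73 (1 of 15 called, 5 adjusted over the list alone) and proliferation genes one of -1.82 (2 of 16 called, 6 adjusted over the list alone), both with adjusted p = 0.0423 with an estimated correlation. Subpallial factors had one of -1.18 (3 of 17 called, 4 adjusted over the list alone, adjusted p = 0.0217). Without 1 day replicate 2 these 3 values became 0.196, 0.196 and 0.158, and without replicate 3 those of pallial and proliferation genes 0.300 and 0.188. The subpallial median was -0.39 without replicate 2 and the pallial one 1.14 without replicate 3. Leaving out any of 9 arrays of other times, none of them of 4 days, took these 2 lists just past the threshold, at 0.0501 to 0.0657. The count was 606 without 1 day replicate 1, 156 without replicate 2, 507 without replicate 3 and 188 without either 8-hour array. Lgi2 lost the call without replicate 2 or 3 (0.113 and 0.0727), Cenpb without replicate 1 or 2 (0.0912 and 0.0994), and Uhrf1 was called in 8 of the 17 fits. Median centring called 143 higher and 693 lower genes and none of the 3 lists (adjusted p = 0.0733 each). The scanner's processed signals called 21 and 7 genes, and with the value table these were 45 and 14. These 2 settings, quantile normalization and the mean over probes ended the pallial call (0.0752 to 0.120), and quantile normalization the proliferation call (0.0899). Without both arrays that stand apart subpallial factors had 0.0618.

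At 2 days (n = 2) 48 genes were called, 39 higher and 9 lower in the dorsal samples. Pcp4 was 5.32 ± 0.72 higher (40.0-fold, adjusted p = 0.0128), the chemokine Cxcl13 4.96 ± 0.69 and Dct 4.76 ± 0.75. Tiam2, a guanine nucleotide exchange factor (-3.54 ± 0.48), Dlx2 (-2.71 ± 0.33, adjusted p = 0.0053) and the actin-binding Tmsb10 (-1.97 ± 0.33) were lower. Pallial factors were higher (median 3.16, 0 of 15 called and 11 adjusted over the list alone, adjusted p = 0.00207 with an estimated correlation). So were astrocyte genes (2.54, 1 of 12 called and 7 adjusted over the list alone, 0.00575) and radial glia genes (1.36, 6 of 17 adjusted over the list alone, 0.00743), while subpallial factors were lower (-1.30, 1 of 17 called and 9 adjusted over the list alone, 0.00115). Glutamatergic neuron genes (1.80, adjusted p = 0.0461), proliferation genes (-1.32, 0.0460) and erythroid genes (3.77, 3 of 6 adjusted over the list alone, 0.0460) were also called. They lost this on leaving out any of 13, 13 and 9 of the 17 arrays, up to 0.141, 0.192 and 0.151 without 2 days replicate 2. Without 2 days replicate 1 the adjusted p was 0.128 for Pcp4, 0.194 for Cxcl13, 0.176 for Dct and 0.10 for Tiam2, and without replicate 2 it was 0.101 for Dct. Tmsb10 was called in 4 of the 17 fits. The count was 79 without replicate 1 and 235 without replicate 2, and the value table called 0 higher and 1 lower. With median centring the radial glia median was 0.62 (adjusted p = 0.431) and the proliferation median -2.09 (0.0643), and glutamatergic and erythroid genes had 0.0527 each. No filter took these last 3 lists to 0.0526 to 0.0659, the stricter filter glutamatergic genes to 0.0602, and the value table, the mean over probes, array weights and the fit without both arrays that stand apart erythroid genes to 0.0510 to 0.0838.

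From 4 days on few genes separated the walls. At 4 days (n = 3) limma called 0 genes (1446 at an unadjusted p under 0.05; 1 to 3 when 1 array of 4 days was left out and 2 with median centring). Pallial factors were higher in the dorsal samples (median 1.18, 3 of 15 adjusted over the list alone, adjusted p = 0.0476 with an estimated correlation). This call was lost on leaving out any of 15 of the 17 arrays, with 0.170 without 4 days replicate 1 (median 0.55) and 0.0617 without replicate 3 (median 1.90). It was lost with median centring too (median 0.66, adjusted p = 0.560), and at 0.0587 to 0.138 with quantile normalization, no filter, the mean over probes or without both arrays that stand apart. Subpallial factors had a median of -0.03 (adjusted p = 0.725). At 7 days (n = 3) 7 genes were called, 6 higher and 1 lower. Among them were the cytochromes P450 Cyp2a4 (4.69 ± 0.65), Cyp2g1 (4.58 ± 0.62) and Cyp2a5 (3.99 ± 0.57), all with adjusted p = 0.0408 and higher on 3 of 3 arrays. Cyp2a4 and Cyp2a5 are close paralogs, so which of them was measured is uncertain, and of the 17 fits that left out 1 array only that without 7 days replicate 2 kept all 3 calls. The highest levels of Cyp2a5 were on 14 days replicate 1 (17.15 dorsal and 16.05 lateral), against 6.80 to 9.58 on the other 14-day arrays. At 14 days (n = 4) 6 genes were called, 1 higher and 5 lower. C1qtnf4, a secreted protein, lay at 4.16 ± 0.57, the neuropeptide precursor Pnoc at -4.26 ± 0.58, the proton pump subunit Tcirg1 at -4.00 ± 0.56 and the immune checkpoint molecule Cd276 at -3.42 ± 0.42, each on 4 of 4 arrays. These were called in 5, 7, 7 and 10 of the 17 fits that left out 1 array. No list was called at 7 or 14 days with an estimated correlation. At 7 days erythroid genes had a median of 3.76 (adjusted p = 0.110), astrocyte genes 0.84 (0.110) and pallial factors 0.34 (0.276). At 14 days the median was 2.31 for ependymal genes (0.117), -0.93 for neuroblast genes (5 of 16 lower adjusted over the list alone, 0.141), -0.80 for GABAergic genes (0.0811) and -1.45 for microglia genes (0.356). The 7-day count was 11, 19 and 19 without 7 days replicate 1, 2 and 3 and 1 or 2 without any other array. The 14-day count was 0 without either array of 8 hours or of 2 days or 7 days replicate 2 or 3, and 22, 15 and 1 without 1 day replicate 1, 2 and 3. It was 3 without 4 days replicate 3, and 16, 56 and 105 without 14 days replicate 2, 3 and 4. Median centring called 1 higher and 2 lower genes at 7 days and 18 and 1416 at 14 days. These were 3 and 1, and 3 and 7, with the scanner's processed signals, and 2 and 1, and 3 and 4, with quantile normalization. The value table gave 3 and 0, and 2 and 5, and without background correction 4 and 0 at 7 days.

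With the spread taken only from the arrays of a time point, limma called 0 genes at each of the 6 time points (3882, 1610, 3573, 1534, 1843 and 1273 at an unadjusted p under 0.05, from 8 hours to 14 days). No list was called either with an estimated correlation (lowest adjusted p = 0.589 at 8 hours, 0.382 at 1 day, 0.619 at 2 days and 0.621 at 4 days for the lists called above). The calls of Dlx2, Dct or Pcp4 at single times therefore rest on the spread pooled over all 17 arrays.

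**Figure D2:**
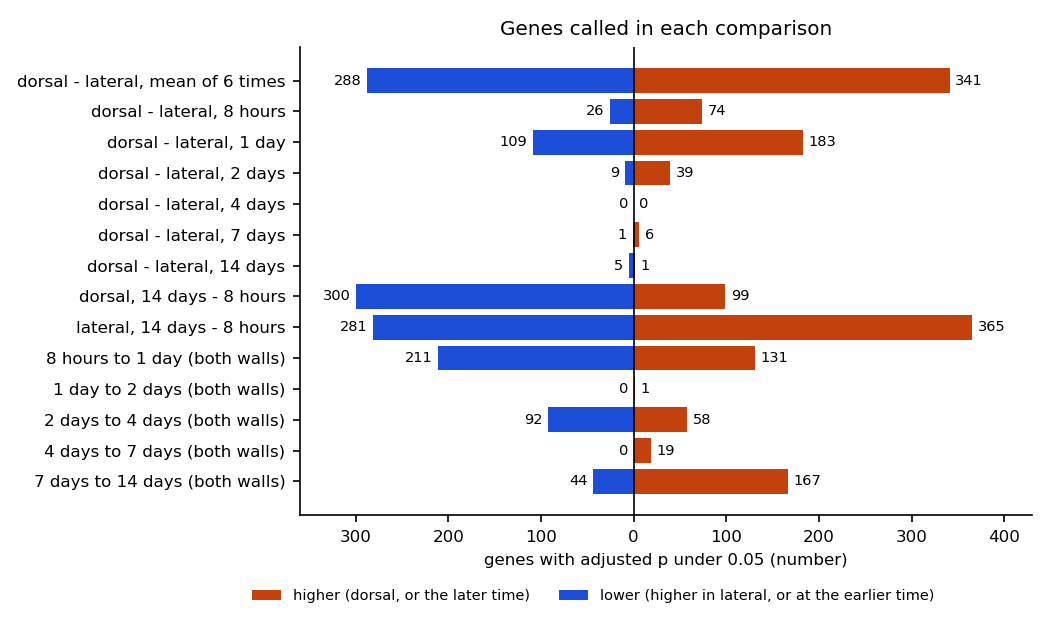
Number of genes called at an adjusted p under 0.05 in each comparison, with genes higher in the dorsal samples or at the later time to the right of 0 and lower ones to the left. The mean wall difference called 341 higher and 288 lower, and the 4-day wall difference 0.

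A further test asked which wall differences changed with time, in which a constant dye effect cancels. Dlx2 lay at -3.99, -3.94 and -2.71 at 8 hours, 1 day and 2 days and at -0.10, -0.17 and -0.99 at 4, 7 and 14 days, a range of 3.88 (adjusted p = 0.0061). Dct (5.08, 4.66 and 4.76, then -0.17, -0.68 and -1.30; adjusted p = 0.0203) and Prrx2 (3.42, 4.65 and 4.06, then -0.18, -0.22 and -0.99; adjusted p = 0.010) lay above 0 at the 3 early times and below it later. For Dct the dorsal level itself fell, from 12.41 to 14.33 up to 2 days to 6.13 to 7.64 from 4 days on. Its negative late means rested largely on 7 days replicate 2 (-2.56) and 14 days replicates 3 and 4 (-3.22 and -1.66). Dorsal Dlx2 instead rose, from 6.75 and 7.33 at 8 hours to between 13.38 and 14.83 at 4 days. Pcp4 differed by 4.26 and 5.32 at 1 and 2 days and lay between -0.98 and 0.67 at other times (range 6.30, adjusted p = 0.0345). Cyp4b1, a cytochrome P450, differed most at 8 hours (4.29; range 4.43), as did the sulfatase Arsj (2.09; range 2.18). The carboxypeptidase Cpn1 differed most at 8 hours and 2 days (2.74 and 2.69; range 2.83), Fam222b at 1 day (3.56; range 4.58), and the neuronal genes Srrm4 and Snap91 at 1 day (2.27 and 3.70; ranges 4.24 and 5.86). In all 26 genes were called. Adjusted over the list alone, 4 of 6 erythroid, 4 of 11 GABAergic, 3 of 17 subpallial and 3 of 16 proliferation genes changed. So did 2 each of the radial glia, neuroblast, mature neuron and endothelial lists, 1 each of the pallial, microglia and Wnt lists, and 0 of the others. The count was 14 and 55 without 8 hours replicate 1 and 2, 65 without 1 day replicate 3, and 92 without 2 days replicate 2. It was 13, 13 and 14 without the 4-day arrays, 16 and 15 without 7 days replicate 2 and 3, and 17, 10 and 16 without 14 days replicate 1, 2 and 3. Pcp4 and Snap91 were called in 7 of the 17 fits and Arsj in 14. Cyp4b1 (0.0544) and Dct (0.0513) lost the call without 8 hours replicate 1 and Fam222b (0.0576) without 1 day replicate 1. Dlx2, Dct, Prrx2 and the other 7 genes named here lost the call with the scanner's processed signals, which called 2 genes (adjusted p = 0.0751 for Dlx2 and 0.0997 for Prrx2), and with the value table, which called 0 (0.110 and 0.126; 1783 genes at an unadjusted p under 0.05). Trend and robust eBayes called 8 genes without Dlx2 (0.0551), and the fit without both arrays that stand apart called 9 without Prrx2 and Dct (0.0542 and 0.0540).

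The next comparison set 14 days against 8 hours within each wall (n = 4 against 2 arrays). Genes of inhibitory olfactory interneurons rose in both lineages. Gad1, a GABA-synthesizing enzyme, rose by 5.50 ± 0.84 in the dorsal and 5.65 ± 0.67 in the lateral samples (45.2- and 50.3-fold). Synpr, a synaptic vesicle protein, rose by 5.40 ± 0.75 and 6.78 ± 0.70, and the transcription factor Sp8 by 4.11 ± 0.75 and 6.30 ± 0.61. Called GABAergic genes numbered 4 higher and 1 lower of 11 in the dorsal (7 and 1 adjusted over the list alone; median 2.44, adjusted p = 0.0481 with an estimated correlation). In the lateral lineage 7 were higher (8 adjusted over the list alone; median 3.85, adjusted p = 0.00781). In the lateral lineage neuroblast genes rose (8 of 16 called, 12 adjusted over the list alone, median 3.40, adjusted p = 0.00781 with an estimated correlation), led by Igfbpl1 (4.21 ± 0.35) and the neuronal tubulin Tubb3 (4.33 ± 0.57). In the dorsal lineage 1 of 16 was called (median 1.60, adjusted p = 0.225 with an estimated correlation). The difference between the walls had an adjusted p of 0.154 with an estimated correlation. In the dorsal lineage oligodendrocyte genes rose (1 of 14 called, 7 adjusted over the list alone, median 3.43, adjusted p = 0.0481 with an estimated correlation). In the lateral lineage their median was 2.86 (adjusted p = 0.375), with Sox10 at 7.44 ± 0.67. The dorsal GABAergic and oligodendrocyte calls were lost on leaving out any of 11 and 13 of the 17 arrays, up to 0.137 without 14 days replicate 3. With only the arrays compared both had an adjusted p of 0.376 and the lateral GABAergic list 0.138. Both were lost at 0.0724 with median centring and at 0.0505 and 0.0527 with no filter, and the GABAergic one at 0.0656 with the scanner's processed signals and 0.0501 without both arrays that stand apart.

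Other genes that rose in both walls were Erbb3, a neuregulin receptor (6.04 ± 0.90 dorsal and 6.15 ± 1.19 lateral), the glutamate receptor Gria1 (5.94 ± 1.21 and 5.62 ± 0.75), the G protein subunit Gng13 (7.50 ± 1.49 and 7.42 ± 1.49). So did Pcp4l1 (6.69 ± 1.1 and 5.99 ± 1.37), St8sia3, a sialyltransferase (5.29 ± 1.09 and 5.29 ± 1.1), the connexin Gjb6 (7.22 ± 1.33, and at least 119-fold in the lateral samples), Nxph1 (at least 40.2-fold, and 5.27 ± 1.07) and Fndc5 (5.71 ± 1.30, and at least 94.3-fold). Among the genes that fell most in both walls, the stefins Cstdc4, Csta1 and Stfa2 were at least 188-, 229- and 244-fold lower at 14 days in the dorsal samples. The calcium-binding S100a8 and S100a9 were at least 203- and 241-fold lower there, and the interleukin-1 receptor antagonist Il1rn at least 234-fold. In the lateral samples S100a9 and Il1rn were at least 276- and 560-fold lower. Stfa1 differed by -7.50 ± 0.53 and -7.50 ± 1.43, and Ptges, a prostaglandin synthase, by -7.60 ± 0.75 and -7.22 ± 1.01. The interferon-induced chemokine Cxcl10, measured on 1 of the 2 8-hour arrays, differed by -9.59 ± 1.96 and -8.08 ± 1.38. The stefins are close paralogs, so which of them was measured is uncertain. Single 14-day samples stood apart from the other 3 in lateral Gng13 (9.34 in replicate 1) and Gjb6 (10.89 in replicate 4), which were lower, and in dorsal Cxcl10 (12.87 in replicate 3), which was higher.

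Of the other lists, several were called only with the preset correlation. In the dorsal lineage the median was -2.30 for microglia (adjusted p = 0.313 with an estimated correlation), -2.19 for erythroid (0.160), -1.25 for radial glia (0.147; Tnc at -4.24 ± 0.78 and Vim at -2.21 ± 0.38), and -1.02 for proliferation genes (0.273). It was 1.85 for mature neuron (0.183; Snap25 at 5.42 ± 0.80) and 0.79 for subpallial genes (0.147; Dlx2 at 5.41 ± 0.71 and Dlx5 at 4.41 ± 0.54). In the lateral lineage it was -2.36 for microglia (0.317; the lysosomal Cd68 at -5.52 ± 1.14) and -1.70 for ependymal genes (0.178; Foxj1 at -4.68 ± 0.80). It was -1.86 for proliferation (0.178) and 2.49 for mature neuron genes (0.0797; Snap25 at 3.94 ± 0.70). Over all genes 399 were called in the dorsal (99 higher, 300 lower) and 646 in the lateral lineage (365 higher, 281 lower), with medians of all genes at 0.21 and 0.31. A total of 46 genes rose in both (1.37 if the lists were independent) and 100 fell in both (3.19), with 0 opposite. A part of this excess may come from the shared arrays, as each wall shares them with the other.

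The 2 8-hour arrays carried much of this comparison. The dorsal count was 77 and 118 without 8 hours replicate 1 and 2, and the lateral count 273 and 272, and 1340 without 1 day replicate 1. With only the arrays compared these counts were 215 and 244. Without 8 hours replicate 1 the dorsal adjusted p was 0.0585 for Synpr, 0.147 for Gad1, 0.0849 for Il1rn and 0.0514 for Dlx2. The highest value was 0.452, for Fndc5 without replicate 2. Called in all fits that left out 1 array were Cstdc4, Csta1, Stfa1, Stfa2, S100a9, Ptges and Dlx5 in the dorsal and Synpr, Gad1, Sp8, Il1rn, Ptges, Gria1, Fndc5, Igfbpl1, Tubb3 and Sox10 in the lateral samples. Cxcl10 kept its lateral call in the fits that could be made, but none could be made without the only 8-hour array that measured it. Each other gene named for this comparison lost its call without at least 1 of the 8-hour arrays. Fndc5 was called in 5 of the 17 fits in the dorsal, and Pcp4l1 in 7 in the lateral samples. The test of whether the change from 8 hours to 14 days differed between the walls called 46 genes, among them Dlx2 (dorsal minus lateral change 3.00, adjusted p = 0.0132), Dct (-6.38, 0.0163) and Dmrta2 (-5.17, 0.0212). It called 0 lists with an estimated correlation (GABAergic genes -1.09, adjusted p = 0.0547).

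**Figure D3:**
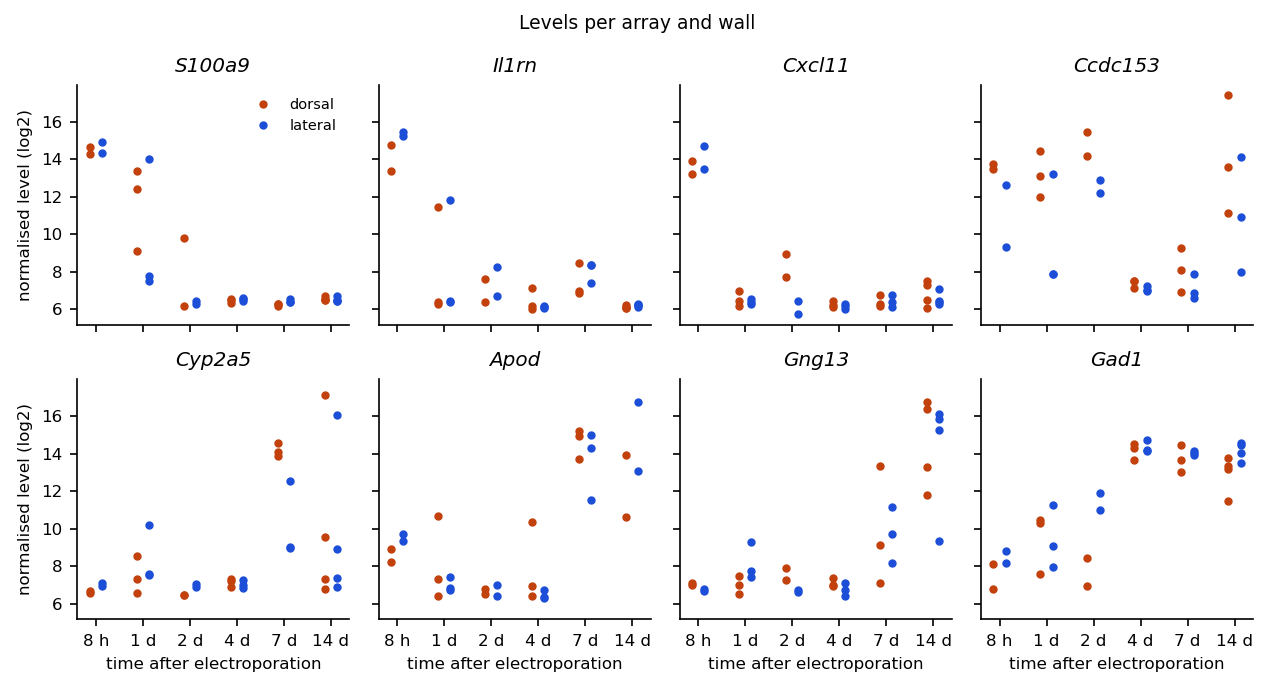
Log2 level of S100a9, Il1rn, Cxcl11, Ccdc153, Cyp2a5, Apod, Gng13 and Gad1 on each array by time, dorsal and lateral samples apart. In both walls S100a9, Il1rn and Cxcl11 were highest at 8 hours, and Gad1 was 5.50 (dorsal) and 5.65 (lateral) higher at 14 days than at 8 hours.

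Over the mean of both walls 1957 genes changed among the 6 time points. Adjusted over the list alone, all 12 astrocyte genes, 14 of 17 radial glia, 12 of 16 neuroblast, 10 of 11 GABAergic and 11 of 13 immediate early genes changed. So did 8 of 14 Notch, 8 of 14 oligodendrocyte, 8 of 11 ependymal, 8 of 16 proliferation, 7 of 15 pallial, 7 of 15 microglia and 6 of 17 subpallial genes. The others had 5 of 20 mature neuron, 4 of 14 Wnt, 3 of 12 dopaminergic, 3 of 10 glutamatergic, 2 each of the transit amplifying, endothelial, choroid plexus and erythroid lists, 1 Zic and septal gene, and 0 Shh, sex-linked and reference genes. The count was 1053 and 993 without 8 hours replicate 1 and 2.

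From 8 hours to 1 day (n = 2 and 3; median of all genes 0.21) 342 genes were called, 131 higher and 211 lower. The interferon-induced chemokine Cxcl11 fell by 7.37 ± 0.33 (adjusted p = 1.51e-07), Retnlg, a resistin-like protein of myeloid cells, by 6.58 ± 0.32 and Il1rn by 6.58 ± 1.13. Mymk, measured on 3 of 5 arrays, rose by 4.81 ± 0.84, the kinase Map2k6 by 3.77 ± 0.73 and Zc3h13 by 3.73 ± 0.76. Of the list members Gsx1 (3.46 ± 0.57), Dlx2 (3.08 ± 0.59) and Igfbpl1 (2.41 ± 0.34) rose. No list was called with an estimated correlation. Microglia genes had a median of -3.61 (9 of 15 lower adjusted over the list alone), pallial factors 1.39 and immediate early genes -0.41 (5 of 13 lower adjusted over the list alone), each at 0.288. Without 8 hours replicate 1 the adjusted p was 0.173 for Il1rn, 0.177 for Map2k6, 0.128 for Gsx1, 0.248 for Dlx2 and 0.085 for Igfbpl1, and without replicate 2 0.116, 0.283, 0.120 and 0.211 for the first 4. Mymk was called in 8 of 16 fits and Zc3h13 in 11 of 17. The count was 63 and 45 without 8 hours replicate 1 and 2, and 172 and 1856 without 1 day replicate 2 and 3. It was 223 without either 2-day array, and 532 and 575 without 14 days replicate 1 and 2. The scanner's processed signals called 28 higher and 98 lower, and with only the arrays compared limma called 0 (2874 at an unadjusted p under 0.05). From 1 to 2 days (median of all genes -0.16) only Ccdc192 was called, at 2.66 ± 0.31 (adjusted p = 0.0221; 2311 genes at an unadjusted p under 0.05), and in 8 of the 17 fits. Microglia genes had a median of 3.21 (adjusted p = 0.398 with an estimated correlation). The count was 104 without 1 day replicate 3, and 2 without 1 day, 2 days or 4 days replicate 1 or 14 days replicate 1 or 2. It was 0 without 2 days replicate 2, 4 days replicate 2 or 3, any 7-day array or 14 days replicate 3 or 4, and with only the arrays compared (1096 at an unadjusted p under 0.05).

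Between 2 and 4 days (n = 2 and 3) GABAergic and neuroblast genes rose and ependymal, astrocyte, radial glia, Notch and immediate early genes fell in the mean of both walls. GABAergic genes rose (3 of 11 called, 5 adjusted over the list alone, median 2.16, adjusted p = 0.00375 with an estimated correlation), with Gad1 at 4.69 ± 0.62 and Synpr at 4.55 ± 0.62. So did neuroblast genes (0 of 16 called, 7 adjusted over the list alone, median 1.44, 0.00918). Ependymal genes fell (5 of 11 called, 8 adjusted over the list alone, median -4.88, 0.00375), among them the cilia genes Dynlrb2 (-7.81 ± 1.06) and Ccdc153 (-6.46 ± 0.85). Falls were also called for astrocyte (3 of 12 called, 7 adjusted over the list alone, -2.08, 0.0253; Gfap -4.80 ± 0.78), radial glia (0 of 17 and 9, -1.61, 0.00780), Notch (0 of 14 and 6, -1.54, 0.00375) and immediate early genes (0 of 13 and 2, -1.34, 0.0439). Sln, a regulator of the calcium pump, was at least 93.2-fold higher at 4 days, and the cystatin Cst12 (5.94 ± 0.81) and Pde4dip (5.40 ± 0.87) rose, while the actin-capping Capg fell by 6.02 ± 0.92. Microglia genes had a median of -2.36 (adjusted p = 0.127 with an estimated correlation), mature neuron genes 0.51 (0.324), glutamatergic neuron genes -0.25 (0.482) and oligodendrocyte genes -0.49 (0.327). A total of 150 genes were called, 58 higher and 92 lower. With the slide as a block 38 were called. All 150 kept their sign within slides 2 and 3 (median sizes 3.32 and 3.27), but were called with these arrays. List medians with the slide as a block, within slide 2 and within slide 3 were 2.06, 2.19 and 2.08 for GABAergic, 1.29, 1.37 and 1.11 for neuroblast and -4.84, -4.01 and -4.84 for ependymal genes. They were -1.84, -1.74 and -1.66 for astrocyte, -1.42, -1.38 and -1.34 for radial glia, -1.55, -0.92 and -1.71 for Notch, -0.74, -0.94 and -1.11 for immediate early and -2.29, -2.52 and -1.57 for microglia genes. With only the arrays of 2 and 4 days none of the 7 lists was called (adjusted p of 0.116 to 0.150). The immediate early call was lost on leaving out any of 12 arrays, with a median of -0.81 without 4 days replicate 1 and -0.68 without replicate 3, and the astrocyte call without 1 day replicate 1 (0.0547). Without both arrays that stand apart these were 0.144 and 0.0696 and with array weights 0.0931 and 0.0517, and the slide as a block, quantile normalization, the stricter filter and the mean over probes took the immediate early list to 0.0578 to 0.0812. Without 2 days replicate 2 the adjusted p was 0.116 for Gad1, 0.124 for Synpr, 0.104 for Ccdc153, 0.131 for Dynlrb2, 0.243 for Gfap, 0.0687 for Cst12, 0.253 for Pde4dip and 0.0988 for Capg. Without replicate 1 it was 0.0841 for Ccdc153, 0.0760 for Dynlrb2, 0.117 for Gfap, 0.112 for Cst12, 0.0592 for Pde4dip and 0.190 for Capg. The count was 17 and 19 without the 2-day arrays, 63, 83 and 44 without the 4-day arrays, and 95 without either 8-hour array. It was 302 without 1 day replicate 1, and 243 and 263 without 14 days replicate 1 and 2. It was 1048 with only the arrays compared.

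Between 4 and 7 days (n = 3 and 3) immediate early and stress genes rose, with 2 of 13 called and 9 adjusted over the list alone (median 1.98, adjusted p = 0.000555 with an estimated correlation), led by Zfp36 (3.69 ± 0.55) and Fos (2.64 ± 0.39). Of all genes 19 were called, all higher at 7 days. Among them were the platelet chemokine Pf4, also a macrophage gene, at least 282-fold, the lipocalin Apod at 6.92 ± 0.93 and the neuropeptide Npy at 6.01 ± 0.76. Of other cell types, microglia genes had a median of 2.88 (8 of 15 adjusted over the list alone, adjusted p = 0.0563 with an estimated correlation), erythroid genes 1.60 (0.0563), endothelial genes 0.64 (0.0762) and choroid plexus genes 1.72 (0.0862). Proliferation genes had one of -1.45 (0.0817), oligodendrocyte genes 0.96 (0.0849) and pallial factors -0.60 (0.0563). With the slide as a block 3 genes were called. All 19 kept their sign within slides 2, 3 and 5 (median sizes 3.37, 4.05 and 3.73). They were called on these arrays, so this is no independent test. The immediate early median was 1.36, 1.82 and 2.68 within these slides. That of microglia genes was 1.98, 2.58 and 3.82. The count was 0 without any 4-day array, 7 and 2 without 7 days replicate 1 and 2, and 2 without either 8-hour array. It was 4 without either 2-day array, and 88 and 33 without 14 days replicate 1 and 2. It was 155 with only the arrays compared. Pf4, Fos, Apod, Zfp36 and Npy were called in 7, 7, 8, 8 and 9 of the 17 fits.

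Between 7 and 14 days (n = 3 and 4; median of all genes 0.16) astrocyte and ependymal genes rose. Astrocyte genes (6 of 12 called, 12 adjusted over the list alone, median 2.95) and ependymal genes (2 of 11 called, 9 adjusted over the list alone, median 2.72) were both called at adjusted p = 0.0380 with an estimated correlation. The glutamate transporter Slc1a2 rose by 3.19 ± 0.38, Gfap by 3.78 ± 0.65 and Ccdc153, not measured on 14 days replicate 1, by 4.93 ± 0.76. The mitochondrial carrier Slc25a18 rose by 6.15 ± 0.96 and Itih3, a hyaluronan-associated protein, by 5.26 ± 0.71. The macrophage gene Mpeg1 fell by 4.79 ± 0.54, Grip1, a receptor scaffold, by 4.38 ± 0.83 and Cd300c2, a myeloid receptor, by 4.25 ± 0.79. Microglia genes had a median of -2.20 (4 of 15 lower adjusted over the list alone, adjusted p = 0.183 with an estimated correlation). The median was 1.79 for oligodendrocyte genes (0.183), and Notch genes had 0.81 (0.132), radial glia genes 0.89 (0.132), neuroblast genes -0.38 (0.132) and GABAergic genes -0.49 (0.132). A total of 211 genes were called, 167 higher and 44 lower. With only the arrays compared limma called 0 (2309 at an unadjusted p under 0.05), and another grouping of these 7 arrays, with 14 days replicate 1 among those of 7 days, called 434. The count was 116 without either 8-hour array, 374 without 1 day replicate 1, 138 without either 2-day array, 38 and 72 without 7 days replicate 1 and 3, and 517 without 14 days replicate 1. Slc25a18 (0.0573 and 0.0526), Ccdc153 (0.0513 and 0.0584) and Gfap (0.108 and 0.0958) lost the call without 7 days replicate 1 or 3. Grip1 and Cd300c2 were called in 11 and 8 of the 17 fits. Without both arrays that stand apart the astrocyte and ependymal lists had adjusted p of 0.180 and 0.194 with an estimated correlation, and both 0.217 with only the arrays compared. With array weights these were 0.0554 and 0.0647, and quantile normalization and the mean over probes took the ependymal list to 0.0594 and 0.0930. On leaving out any of 7 and 8 arrays they lost the call, up to 0.0974 without 1 day replicate 1.

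**Figure D4:**
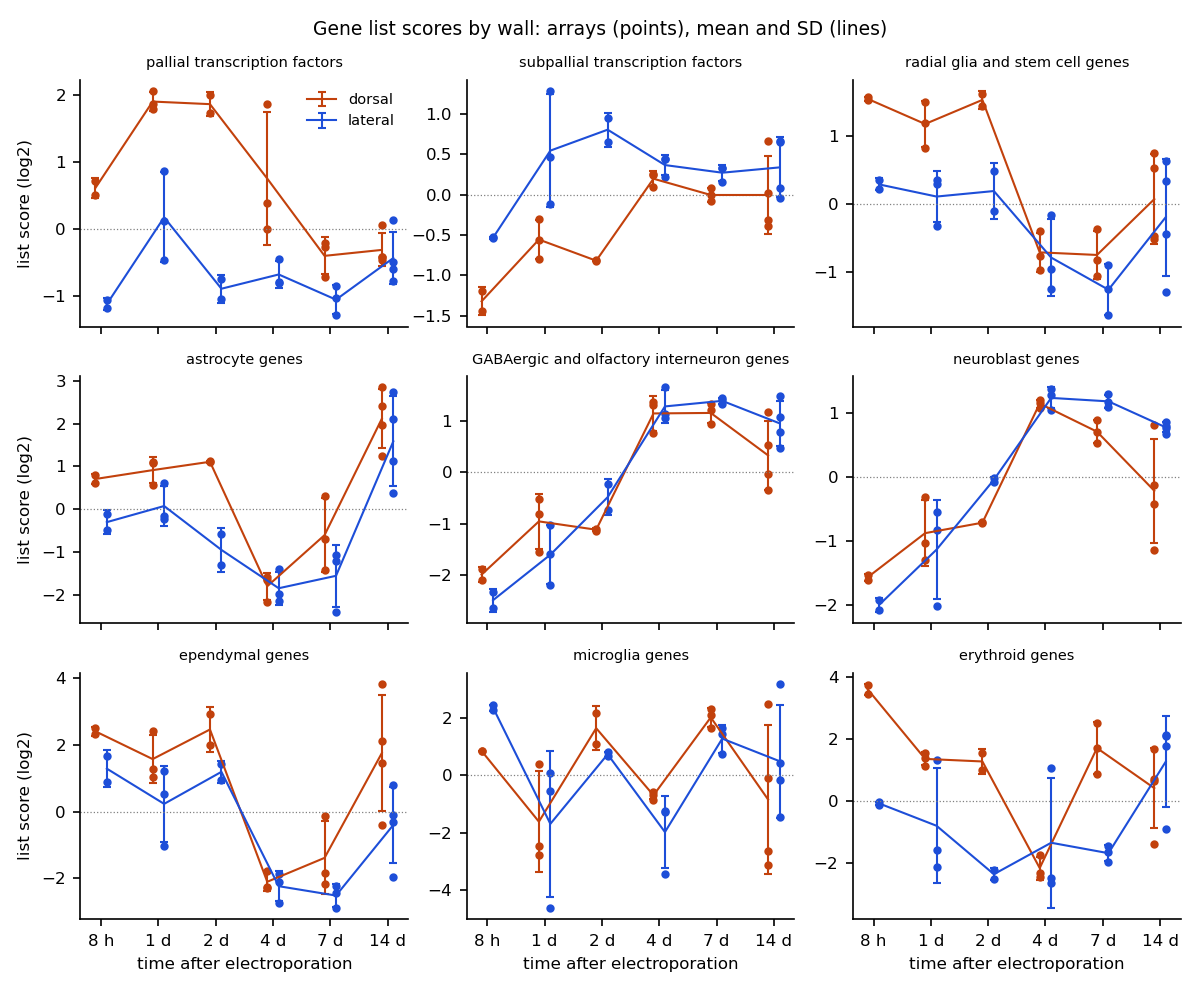
Mean log2 level of 9 gene lists in the dorsal and lateral samples by time, each relative to its mean over all samples; points are arrays and lines the mean with its SD. Ependymal genes lay at 2.46 in the dorsal samples at 2 days, at -2.10 at 4 days and at 1.75 at 14 days, where the SD was 1.75.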

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

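The tests of noise, of a constant dye effect and of olfactory sensory neurons in the dorsal samples were chosen only after the result was seen.

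A total of 100 genes fell from 8 hours to 14 days in both walls, among them S100a9, Il1rn and Ptges, while the microglia list, with medians of -2.30 in the dorsal and -2.36 in the lateral samples, was not called (adjusted p = 0.313 and 0.317 with an estimated correlation). Slide 5, which held both 8-hour arrays, was argued against, as these 100 genes lay a median of 4.82 higher at 8 hours than on the 4- and 7-day arrays of other slides, whereas the 4- and 7-day arrays of slide 5 differed from those by -0.11, or -2.24% of that excess (quartiles -8.75 and 0.938%). An interferon response gave what it needed, as 16 interferon response genes outside the named ones had medians 4.69 higher at 8 hours than at 14 days in the dorsal and 5.72 in the lateral samples, with 16 of 16 higher in each (from 8 hours to 14 days Ifit1 differed by -6.64 and -8.20, and Usp18 by -6.89 and -6.13). It is a candidate explanation for genes of that response, but the test does not show that it accounts for S100a9, Il1rn or Ptges. At 1 day the interferon list had a dorsal mean of 14.07. Dorsal Il1rn then lay at 6.41, 6.29 and 11.48, and dorsal S100a9 at 9.10, 12.41 and 13.39. Neutrophils among the sorted cells stayed open, since 16 neutrophil genes had medians of 1.49 and 1.87 with quartiles of -1.13 and 3.25 in the dorsal samples, where 10 of 16 were higher at 8 hours: from 8 hours to 14 days Fpr2 (-6.19 dorsal), Clec4d (-4.82) and the granule genes Mmp8 (-3.23, limma adjusted p = 0.0364), Ngp (-2.18) and Camp (-1.23) went that way and the granule genes Elane (1.17) and Mpo (1.11) did not. Of these granule genes only Mmp8 was called (limma adjusted p = 0.287 for Elane and 0.453 for Mpo). Genes named by the rule, such as S100a8, S100a9 and the stefins, were left out of this list although they fell. The sort for GFP is meant to remove neutrophils, but its purity was not measured here. Of the 16 genes of either list 0 stood in another list. The age of the animals and a response to the electroporation were not tested, as samples without it were not used here.

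At 7 days the cytochromes P450 Cyp2a4, Cyp2g1 and Cyp2a5, known from the olfactory mucosa, were higher in the dorsal samples, Cyp2a5 was highest on 14 days replicate 1 (17.15 dorsal and 16.05 lateral, against 6.80 to 9.58 on the other 14-day arrays), and Apod and Npy rose from 4 to 7 days in the mean of both walls. RNA of olfactory sensory neurons stayed open. In the mean of both walls the median of 9 of their genes outside the named ones changed by 0.32 from 4 to 7 days, the highest, Adcy3, by 0.93 and Omp, an abundant one, by -0.16, against 6.92 for Apod. In the dorsal samples the median was 0.53 with quartiles of 0.17 and 1.23 (Adcy3 1.78, Rtp1 1.31, Ano2 1.23 and Omp -0.84). The test left out named genes, among them the G protein subunit Gng13. At 7 days Gng13 lay at 13.36, 7.11 and 9.16 in the dorsal and 9.74, 11.18 and 8.16 in the lateral samples, against 6.44 to 7.35 at 4 days. RNA of support cells and glands of the olfactory epithelium stayed open, since the median of 9 of their genes in the dorsal samples was 0.55 with quartiles of 0.01 and 1.19, while Cbr2 differed by 6.20 in the mean of both walls (limma adjusted p = 0.262). RNA of olfactory ensheathing cells stayed open too, as the median of 6 of their genes was 0.19 with quartiles of -0.04 and 1.07, while Sox10 (3.50, limma adjusted p = 0.239), seen beforehand and kept apart, lay above it. The sort for GFP is meant to remove cells without the plasmid, but its purity was not measured here. A change of the labelled cells with time, the difference the design names, was not tested against these explanations.

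Wall differences agreed between replicates at 8 hours and 2 days and less so at 4 to 14 days: across genes the log ratios of replicates correlated at 0.40 at 8 hours and 0.38 at 2 days (1 pair each), and at means of 0.05, 0.09 and 0.03 at 4, 7 and 14 days, while at 1 day the mean was 0.08 and the covariance of the 3 pairs ran from -0.0063 to 0.435. More noise at 4 and 7 days would lower the correlation by raising the variance and leave the covariance as it was, and was argued against as the whole cause, as the variance was 1.22 at both times against 1.15 at 2 days and the mean covariance 19.1% of that of the single pair at 2 days (0.0528 and 0.105 against 0.415). The part not shared by replicates was thus larger at 4 and 7 days, so noise as a part of the cause stays open. The 14-day arrays, with a variance of 2.25, were not in this test. A constant dye effect would give arrays of different times the same covariance as replicates. That covariance, 0.0733, was 20.5% of the 0.358 at 8 hours (16.8 to 23.0% without 1 array). This argued against it as the main source at 8 hours and 2 days. At 4 to 14 days (0.0528 to 0.105) it stays open. Lineages that grow more alike after 2 days are a candidate explanation, found on the same data, though 1 day lacks the agreement. Handling shared by the replicates of 8 hours or of 2 days stays open, as no test separates them. So does a weaker dorsal signal at other times, with array medians of 30.3 to 194 against 185 to 310.

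At 14 days, the time with 4 arrays, 8 of 70 quantities had an array far from the other 3, where chance gives about 1 in 20. The share of probes well above background in the dorsal sample was 41.5% in replicate 2, against 60.1 to 62.9% in the others. The mean log ratio of sex-linked genes was 1.25 in replicate 1, against -0.46 to -0.40. The log ratio of Cd276 was -4.13 in replicate 4, against -3.24 to -3.13. The lateral level of Stfa1 was 7.70 in replicate 2, against 6.49 to 6.66. The dorsal level of S100a9 was 6.71 in replicate 4, against 6.50 to 6.53, though it was well above background on none of these arrays. The lateral level of Gjb6 was 10.89 in replicate 4, against 13.31 to 13.80, and that of Gng13 was 9.34 in replicate 1, against 15.28 to 16.14. The dorsal level of Cxcl10 was 12.87 in replicate 3, against 6.26 to 7.24.

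The wall difference of 26 genes differed between time points by limma's F test. The ranges of the time-point means of the 10 with the smallest p-values were 3.88 for Dlx2, 2.83 for Cpn1, 4.43 for Cyp4b1, 5.64 for Prrx2, 4.58 for Fam222b, 6.38 for Dct, 4.24 for Srrm4, 2.18 for Arsj, 6.30 for Pcp4 and 5.86 for Snap91.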

How the results depend on the processing

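The fit without both arrays that stand apart was chosen only after the data were seen. Counts of called genes, all from limma, are given below where an alternative moved them by over 1.5 times, against 629 for the mean wall difference, 100, 292, 48, 0, 7 and 6 for the wall differences from 8 hours to 14 days, 26 for their changes with time, 399 and 646 for 14 days against 8 hours in the dorsal and lateral samples, 1957 for the time course, and 342, 1, 150, 19 and 211 for the steps from 8 hours, 1, 2, 4 and 7 days. Of 533 counts under alternatives 280 stayed within 1.5 times and 253 moved. Of 7001 values of named genes 5390 kept direction and call, 1605 lost the call and 6 turned. Of 10560 list values 10070 kept direction and call at the preset correlation, 295 lost the call, 187 gained it and 8 turned. The share of probes well above background, 41.5 to 77.0% in the dorsal samples, limits what is measured: 26458 genes were tested and 18950 with the stricter filter, and the log ratios varied most at 1 and 14 days (variances of 2.60 and 2.25). No value is given for the mean wall difference, its changes and the time course with only the arrays compared, as they use all arrays. Except where fewer genes or arrays entered, the cause was not tested.

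With the scanner's processed signals the counts were 237 for the mean wall difference, 39, 28, 26, 4 and 10 at 8 hours, 1, 2, 7 and 14 days, 2 for changes with time, 250 and 405 for 14 days against 8 hours, and 126, 0, 86 and 124 for the steps from 8 hours, 1, 2 and 7 days. With no background correction they were 4 at 7 days, 13 for changes with time and 0 for the step from 1 day. The value table gave 282 for the mean and 6, 59, 1 and 3 at 8 hours, 1, 2 and 7 days, and 0 changes with time (1783 at an unadjusted p under 0.05). Median centring gave 6146 for the mean, 836, 13, 2, 3 and 1434 at 1, 2, 4, 7 and 14 days and 11 for changes with time, and called 15 list results with an estimated correlation against 36. Quantile normalization of all channels gave 45, 21 and 3 at 8 hours, 2 and 7 days and 10 changes with time. No filter gave 1 at 7 and 3 at 14 days, 51 changes and 2 for the step from 1 day. The stricter filter, with fewer genes, gave 385 for the mean, 7, 6 and 0 at 8 hours, 2 and 7 days, 7 changes, 209 in the dorsal samples, 159 for the step from 8 hours and 0 from 1 day. The mean over probes moved no count past 1.5 times. Trend and robust eBayes gave 232 for the mean, 136, 26, 1 and 0 at 1, 2, 7 and 14 days and 8 changes.

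Array weights gave 1585 for the mean, 765, 21, 378, 16 and 1 at 8 hours, 1, 2, 7 and 14 days, 353 changes, 1610 and 2163 for 14 days against 8 hours, 18493 for the time course and 14498, 9380, 2227, 200 and 432 for the steps. The slide as a block gave 3293, 392, 2546 and 2135 for the mean, 8 hours, 1 day and 14 days, 529 changes, 4346 and 4560 for 14 days against 8 hours, 13247 for the time course and 6750, 22, 38, 3 and 1119 for the steps, with consensus correlations of -0.17 for the log ratio and -0.22, -0.25 and -0.24 for the dorsal, lateral and mean levels, so that the larger counts rest on correlations below 0. With only the arrays compared, the counts were 0 at 8 hours, 1, 2, 4, 7 and 14 days (1273 to 3882 at an unadjusted p under 0.05), 215 and 244 for 14 days against 8 hours, 1048 and 155 for the steps from 2 and 4 days, and 0 for those from 8 hours, 1 and 7 days (2874, 1096 and 2309 unadjusted), and 3 list results against 29 among the same comparisons. Without both arrays that stand apart, the counts were 1381 for the mean (602 shared with the 629), 713, 0 and 27 at 1, 7 and 14 days, 9 changes, 648 and 1404 for 14 days against 8 hours, 3390 for the time course and 587, 2, 605, 40 and 508 for the steps.

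Leaving out 1 array at a time moved the counts between 213 and 1152 for the mean, 63 and 190 at 8 hours, 156 and 606 at 1 day, 39 and 235 at 2 days, 0 and 3 at 4 days, 1 and 19 at 7 days, 0 and 105 at 14 days, 10 and 92 for changes, 77 and 581 and 272 and 1340 for 14 days against 8 hours in the dorsal and lateral samples, and 993 and 2569 for the time course. The steps ran between 45 and 1856, 0 and 104, 17 and 302, 0 and 88, and 38 and 517, and the called list results between 24 and 37. Where this left a time point with 1 array, that array was assumed to vary like the others.

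The replicate number did not pair the arrays: of 36 same-numbered pairs at different times, 0 had a correlation of residuals over 0.1 for the log ratio and 5 for the mean level, and 10 and 9 of 17 arrays correlated best with their own number. For the title's letter these were 0 and 6 of 29 pairs and 4 and 10 arrays. With the number as a replicate block the counts were 173 for the mean, 33, 100, 1, 1, 0 and 41 at 8 hours to 14 days, 0 changes, 720, 0, 85 and 4 for the steps from 8 hours, 1, 2 and 4 days, and 16 list results. With the letter as a replicate block they were 114 for the mean, 5, 59, 0, 0 and 0 at 8 hours, 1, 2, 7 and 14 days, 0 changes, 1007 in the dorsal samples, 2574, 7, 91 and 2 for these steps, and 16 list results. Erythroid medians with the number and the letter block were 0.77 and 0.34 in the mean wall difference and 2.24 and 0.78 at 8 hours, against 1.56 and 4.96. With the number block the median of microglia genes at 7 days went from 0.80 to -0.0278, and the camera test of oligodendrocyte genes in the mean wall difference turned while their median went from 0.63 to 0.39. With the letter block Hbb-bt went from 3.70 to -1.37 and Gria2 from 1.65 to -0.27 in the mean wall difference.

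Other values turned as well, and like those with the blocks they were not called there (lists by the preset correlation). With median centring Igfbpl1 in the mean wall difference went from 0.81 to -0.18, radial glia genes at 1 day from 0.85 to -0.0591, mature neuron genes at 4 days from 0.12 to -0.39, and immediate early genes from 0.53 to -0.14 at 4 days and from 0.54 to -0.37 at 7 days. With the mean over probes, where other probes of a gene enter, Kl went from -0.30 to 0.0112 and Hydin from -0.60 to 0.19 in the mean wall difference, and Slc1a3 from 2.74 to -0.96 in the step from 7 to 14 days. With the stricter filter the endothelial list in the lateral samples went from -0.14 to 0.47, and without 7 days replicate 2 the choroid plexus list at 7 days from 1.19 to -0.0600, with up to 2.21 without replicate 1.

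Chance was excluded for the mean wall difference, where turning the sign of arrays at random gave as many genes in 1 of 100 draws, the real one (629, highest other 124). Chance was not excluded where regroupings called more genes, with shares unadjusted. These were changes with time (3 of 100, 26, highest other 97) and the time course (2 of 100, 1957, highest other 3604). Both largest draws set 1 day replicate 1 and 14 days replicate 2 apart. The step from 7 to 14 days (2 of 35 splits, 211, highest other 434) was another. Its larger split set 14 days replicate 1 with the 7-day arrays. The splits were too few for a share under 0.05 at 1 day (1 of 4; 292, highest other 23), 4 days (4 of 4; 0 and 1), 7 days (2 of 4; 7 and 9), 14 days (2 of 8; 6 and 8) and the step from 4 to 7 days (1 of 10; 19 and 0).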

Other observations

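The regional score below and its tests were chosen only after the data were seen.

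Interferon response genes, 16 in all and outside the 24 lists, had higher mean levels from 8 hours to 2 days than from 4 days on in both lineages, though the times between were not compared by a test. Their mean log2 level was 14.60 ± 0.04 (SD, n = 2) in the dorsal and 14.82 ± 0.25 in the lateral samples at 8 hours, 14.07 ± 0.23 and 12.65 ± 0.55 at 1 day (n = 3) and 13.09 ± 0.40 and 11.20 ± 0.14 at 2 days (n = 2). At 4 days it was 8.88 ± 0.59 and 8.75 ± 0.93, at 7 days 9.74 ± 0.33 and 8.43 ± 0.39 (n = 3), and at 14 days 10.06 ± 1.68 and 9.44 ± 0.83 (n = 4). The gap between the walls at 1 and 2 days was not tested as a list. From 8 hours to 14 days Ifit2, an antiviral gene, differed by -5.18 in the dorsal and -6.38 in the lateral samples (limma adjusted p = 0.0153 and 0.00255), and Mx1, an antiviral GTPase, by -4.68 and -4.87 (0.0145 and 0.00106).

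Of 6 erythroid genes, 4 changed in their wall difference with time adjusted over the list alone. In the dorsal samples the mean of the list, relative to its mean over all samples, was 3.59 ± 0.18 (SD, n = 2) at 8 hours, 1.36 ± 0.21 at 1 day (n = 3), 1.27 ± 0.41 at 2 days (n = 2), -2.16 ± 0.37 at 4 days, 1.70 ± 0.83 at 7 days (n = 3) and 0.42 ± 1.28 at 14 days (n = 4). In the lateral samples it was -0.08 ± 0.06, -0.80 ± 1.85, -2.35 ± 0.20, -1.34 ± 2.10, -1.68 ± 0.25 and 1.27 ± 1.46 at these times, so that the lateral mean was the higher one at 4 and 14 days. Dopaminergic periglomerular genes, of which 3 of 12 changed over time adjusted over the list alone, lay at -0.54 ± 0.28 in the dorsal and -0.69 ± 0.16 in the lateral samples at 1 day (n = 3) and at 0.48 ± 0.68 and 0.66 ± 0.51 at 14 days (n = 4).

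A regional score, the mean log ratio of pallial minus that of subpallial factors on each array, fell with the logarithm of time over the 17 arrays (Pearson r = -0.68, two-sided permutation p = 0.00283, adjusted p = 0.00699 over 3 relations; Spearman rho = -0.77, p = 0.00043, adjusted p = 0.00121), and was above 0 on 16 of 17 arrays. Without the 8-hour arrays r was -0.78. The score rose to 2 days before it fell. Its pallial part alone gave r of -0.66 (permutation p = 0.00466) and rho of -0.75 (0.00081), and its subpallial part 0.53 (0.0285) and 0.63 (0.00746). The pallial part had means of 1.74, 1.73, 2.76, 1.43, 0.66 and 0.12 from 8 hours to 14 days, and the subpallial part -0.79, -1.10, -1.62, -0.17, -0.28 and -0.34. Within slide 2 the score was 4.55, 2.62 and 0.47 at 2, 4 and 7 days, and on slide 3 4.21, 1.03 and 1.17. On slide 5 it was 2.61 and 2.44 at 8 hours and 1.16 on each array of 4 and 7 days. Arrays of 1 and 14 days filled other slides.

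The change from 8 hours to 14 days differed between the walls for 46 genes (1849 at an unadjusted p under 0.05). Beyond those named before, and chosen after their values were seen, they included Reg4 (dorsal minus lateral change -4.05, limma adjusted p = 0.00718), the neuropeptide precursor Tac1 (-2.26, 0.0064), the cytokine Tnfsf4 (2.57, 0.0064) and the transcription factor Gata2 (2.85, 0.0379).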
